A study of Homo sapiens with 48 samples.

How the data were processed

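Gene expression was measured by RNA sequencing in 48 libraries from 4 lymphoma cell lines, each grown with 4 treatments in 3 replicates. Per the labels' protocols, poly(A) RNA was made into stranded libraries with an xGen kit after 6 days of treatment, with cells reseeded during that time. Per the submitters' processing notes, reads were handled with STAR and the GRCh38 (hg38) build; DESeq2 is also named there without its role. The versions of these tools, the counting program, its strand setting and the annotation release are not given in the sources used here, and neither are the inhibitor doses. The deposited table holds raw read counts for 37706 Ensembl genes in 48 columns, without normalization; its values were checked to be whole numbers. Of these genes 17598 are protein coding, and 10169 have no symbol in the table and are named by their Ensembl identifier. Each column was assigned to its group from its header, which carries the line, the treatment and the replicate number. The growth protocol names Oci-Ly8 in 2 places and does not name Oci-Ly7, so the line names used here are those of the sample labels.

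Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr on the 16 groups, which kept 17749 genes, 13502 of them protein coding. Libraries were scaled with TMM, 16 group means were fitted with 32 residual degrees of freedom, and contrasts were tested with edgeR's quasi-likelihood F test with robust shrinkage. A gene is called when its Benjamini-Hochberg adjusted p is under 0.05 over all genes tested. Averaged comparisons use the mean of the contrasts of the 4 lines, so that each line has equal weight. The 3 treatments were compared with DMSO, and the combination with each inhibitor. Non-additivity was tested as the combination minus both single effects on the log2 scale. DOT1Li, EZH2i and the combination were also compared with DMSO in each line, and differences between lines in each treatment effect were tested with an F test. Standard errors are the size of the log2 fold change over the square root of F. Levels are counts scaled to a common library total (CPM), and log2 CPM used a prior count of 2.

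A gene without counts in the compared groups of any line cannot be called in the averaged test. This left 85.1% of genes open to a call for DOT1Li, 86.16% for EZH2i and 87.8% for the combination against DMSO. A setting chosen after seeing the data averages such a gene over the lines that have counts. Where all 3 libraries of a group have 0 counts, a fold change is given as a lower bound against a floor of 3 counts over the group, and the fitted fold change of such a gene depends on the prior count.

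The 23 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most of the other settings tried. They hold Polycomb developmental targets, Polycomb-silenced genes in germinal centre B cells, germinal centre, pan-B, plasma cell and memory or exit genes, MHC class I and II, interferon response, cell cycle, MYC and nucleolar genes, cholesterol biosynthesis, p53 targets, amino acid and unfolded protein stress, PRC2 subunits, DOT1L and its partners, and markers of T, NK, myeloid, erythroid or megakaryocytic, epithelial, fibroblast or endothelial, and neuronal cells. The lists were written from general knowledge and not from these libraries. Lists were compared with the other genes by camera in limma 3.58.1 with its preset inter-gene correlation, and again with an estimated correlation; adjusted p-values of lists are over the 23 lists of a comparison. Named genes are a fixed panel (DOT1L, EZH2, BCL6, MYBL1, MME, PAX5, EBF1, MS4A1, PRDM1, IRF4, XBP1, SDC1, JCHAIN, CD38, CIITA, CDKN1A, MYC, BCL2 and a gene not reported here) and the 5 highest and 5 lowest called protein-coding genes with an average log2 CPM of at least 1 and the same sign in 4 lines. Up to 3 called members of each list with the smallest adjusted p, 3 genes in each direction for the combination within each line, the 3 genes with the smallest p for each difference between lines, and 5 genes in each direction shared by both inhibitors complete the rule.

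Clustering used the 1000 most variable genes, 1 minus the Pearson correlation and average linkage, and was compared with the labels by the adjusted Rand index. Principal components were computed on log2 CPM, over all libraries and after subtracting each line's mean. Exonic lengths from GENCODE 29 were found for 17286 of the tested genes (97.39%). Simulated data with known changes were used to test the code: at a true log2 change of 1, 35 of 40 genes were recovered for DOT1Li in the averaged test and 71 of 80 for the combination, with 1 and 4 false calls. For the combination against EZH2i 71 of 80 were recovered at a change of 1 and 33 of 40 at 0.5, with 11 false calls. In a single simulated line 62 of 80 were recovered for DOT1Li.

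Other settings fixed in advance were DESeq2 1.42.0, DESeq2 size factors in the edgeR fit, no filter on low counts, a replicate block, an additive model of line and treatment, a separate fit for each line, other thresholds for shared genes, other clustering settings, and leaving out each library in turn. Settings chosen after seeing the data were leaving out 2 Oci-Ly8 libraries with few counts from long transcripts, leaving out 2 Oci-Ly7 libraries with a weaker DOT1Li response, a correction for gene length, and the averaging over lines with counts.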

Results

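RNA was sequenced from 4 cell lines of diffuse large B cell lymphoma of the germinal centre B cell type, Oci-Ly7, Oci-Ly8, SUDHL6 and Oci-Ly18. Cells were treated for 6 days with DMSO, the vehicle, with the DOT1L inhibitor EPZ-5676 (DOT1Li), with the EZH2 inhibitor GSK343 (EZH2i), or with both (the combination). Each of the 16 groups has 3 libraries. DOT1L is the histone methyltransferase that marks the bodies of transcribed genes, and EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which silences genes. Library totals ran from 5174269 to 18845074 counts with a median of 14499938. Oci-Ly8 DOT1Li replicate 3 was the shallowest, and the next had 11391942. Between 17214 and 22853 genes had counts in a library. A count of 0 in all 3 libraries of a group allows up to 3 counts, which is 0.0632 CPM in Oci-Ly7 DMSO, and such floors cover counting error only. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these libraries. In Oci-Ly8, DMSO replicate 3 and DOT1Li replicate 3 had fewer counts from long transcripts than the other 46 libraries, with a slope of log2 CPM on log2 exonic length of -0.223 and -0.195 against at least -0.0482. In the other lines the inhibitor effects do not draw on these libraries directly, but they share the estimate of spread.

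The study asked how inhibition of DOT1L and EZH2 acts on B cell identity and grouped its libraries without supervision. Here all libraries clustered by cell line (adjusted Rand index 1). Within lines the 4 clusters matched the 4 treatments fully in Oci-Ly18 (index 1) and less closely in Oci-Ly7 (0.753), Oci-Ly8 (0.543) and SUDHL6 (0.543). In Oci-Ly7, DOT1Li replicate 1 clustered with the DMSO libraries. In Oci-Ly8 and in SUDHL6 all EZH2i and combination libraries shared a cluster. Oci-Ly8 DOT1Li replicate 3 and SUDHL6 DMSO replicate 3 each formed a cluster alone. With line means removed, the first component held 36.7% of the variance and ordered the treatments. Its mean was -19.73 ± 3.17 for DMSO, -5.83 ± 3.60 for DOT1Li, 2.77 ± 1.82 for EZH2i and 22.78 ± 5.71 for the combination (SD, n = 12).

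**Figure D1:**
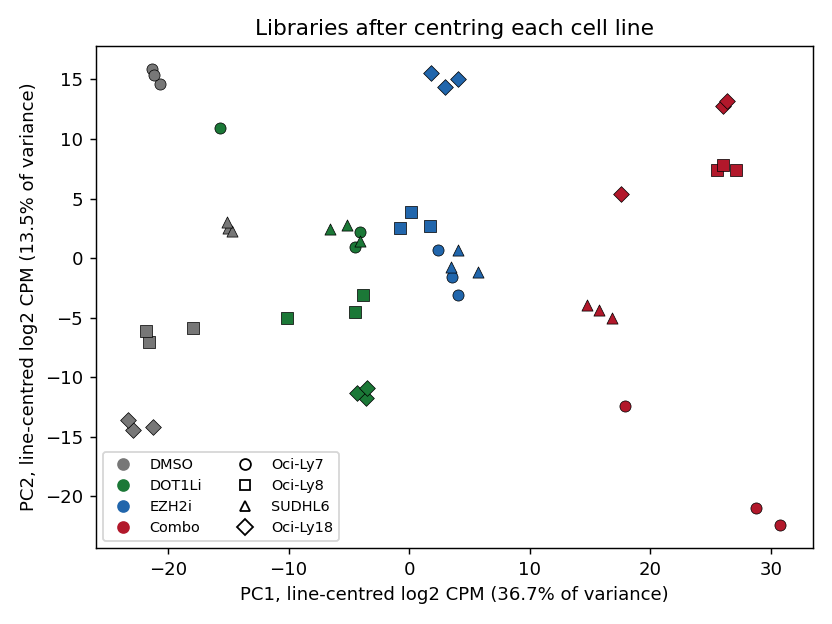
Principal components 1 and 2 of log2 CPM after removing each line's mean, as unitless scores, with 1 point per library, colour for treatment and shape for cell line. On average DMSO libraries lie lowest on the first component (mean -19.73) and combination libraries highest (mean 22.78), with both single inhibitors between them. Oci-Ly7 DOT1Li replicate 1 (-15.66) lies below the SUDHL6 DMSO libraries (-15.13 to -14.67).

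The comparisons with DMSO ask what each inhibitor and their combination change on average over the 4 lines. With DOT1Li 902 of 17749 genes rose and 922 fell, with EZH2i 2787 rose and 2223 fell, and with the combination 4569 rose and 3667 fell (edgeR, adjusted p under 0.05). Large changes were mostly rises: among called genes with a log2 fold change of at least 1 in size, 123 rose and 5 fell with DOT1Li, 449 and 25 with EZH2i, and 1392 and 31 with the combination. The 5 falls with DOT1Li are HCST, ENSG00000258674, ENSG00000243696, ENSG00000279539 and RN7SKP173, named after their values were seen; they numbered 2 without Oci-Ly18 DOT1Li replicate 1, and 3 without Oci-Ly7 DMSO replicate 1, EZH2i replicate 1, 2 or 3 or combination replicate 2, Oci-Ly8 combination replicate 2, SUDHL6 DOT1Li replicate 2, or Oci-Ly18 DMSO replicate 1, EZH2i replicate 1 or 2. The median log2 fold change of all genes stayed near 0, at 0.011, 0.030 and 0.078. Averaging over lines with counts, which lets genes silent in some line be called and changes the adjusted p of the others, gives 1200 higher and 981 lower with DOT1Li, 3334 and 2335 with EZH2i, and 5398 and 3783 with the combination.

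**Figure D2:**
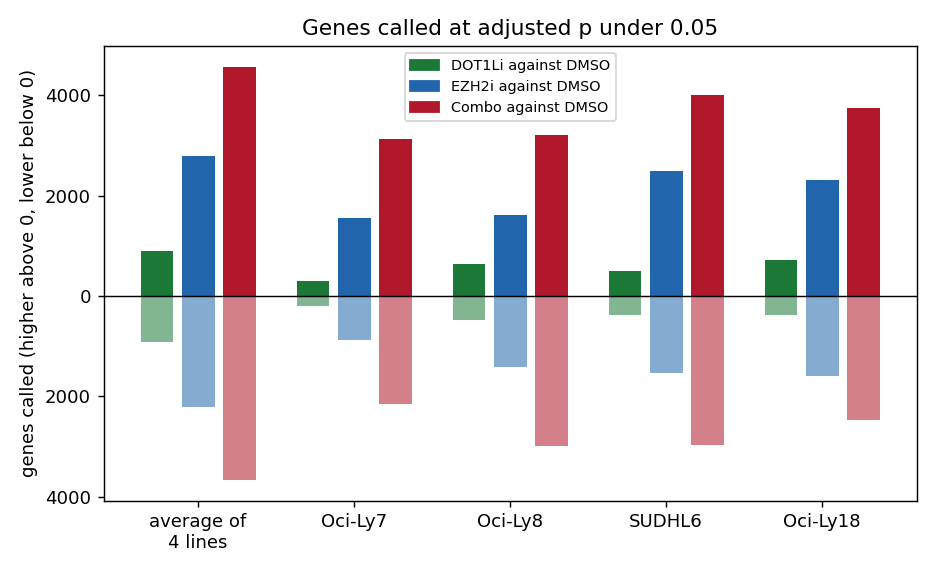
Number of called genes (y axis; higher than DMSO above 0, lower below) for DOT1Li, EZH2i and the combination, averaged over 4 lines and in each line. The combination has the most calls in every set of bars, with 4569 genes higher and 3667 lower on average.

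DOT1Li raised interferon-response genes and lowered genes of ribosome production, amino acid supply and protein folding on average, while it also raised PRDM1, which encodes the transcription factor BLIMP1 of plasma cells. PRDM1 (ENSG00000057657, GRCh38 chromosome 6, 105993463 to 106109939) was 2.03-fold higher (log2 fold change 1.02 ± 0.16 SE, adjusted p = 1.22e-05), with a rise in each line of between 0.72 and 1.41. The antiviral GTPase MX1 (ENSG00000157601, chromosome 21, 41420020 to 41470071) was 2.44-fold higher, and in SUDHL6 its level went from 9.02 ± 0.17 to 24.7 ± 4.27 CPM (SD, n = 3). XBP1, a factor of the secretory programme, fell by 0.39 on the log2 scale, and JCHAIN, which joins secreted antibodies, fell by 0.55. MYC fell by 0.22, while the apoptosis inhibitor BCL2 rose by 0.30. The target itself was little changed in transcript, as DOT1L fell by 0.15 and EZH2 fell by 0.09. BCL6, the repressor that defines germinal centre B cells, was at -0.13 and IRF4 at -0.10, neither past the test.

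The named genes with the largest average rises were LTBP2 (2.25), CMPK2 (2.14), CHL1 (2.03), MVB12B (2.03) and CCDC187 (1.74), as log2 fold changes. CMPK2, MVB12B and CCDC187 have no counts in Oci-Ly7 DMSO, so their averages depend on the prior count, and CMPK2 in that line was at least 1.99-fold higher. Falls were small: the deubiquitinase USP7 fell by 0.54 ± 0.05, ALDOC, a glycolytic aldolase, by 0.56 and FGD6 by 0.52. Of the 44 interferon genes 13 rose (17, adjusted over the list alone; camera adjusted p = 3.51e-09), including MX2 at 0.41 and OAS3 at 0.59. Among MYC and nucleolar genes 15 of 30 fell (21, adjusted over the list alone; camera adjusted p = 2.24e-14), with LDHA at -0.22 and the ribosome assembly gene BYSL at -0.23. Called members by line, without a test between lines, were 17 of the 30 lower in SUDHL6, 3 in Oci-Ly8 and 0 in Oci-Ly7 and Oci-Ly18, and for interferon 13 higher in Oci-Ly8, 8 in Oci-Ly18, 4 in SUDHL6 and 1 in Oci-Ly7. Of the stress genes 14 of 26 fell (17, adjusted over the list alone; camera adjusted p = 1.69e-11); SLC7A5 and SLC3A2, which form an amino acid transporter, fell by 0.43 and 0.23, and the folate enzyme MTHFD2 by 0.20. Plasma cell genes went down as a group by the test (camera adjusted p = 5.56e-05), with 9 of 30 lower and 2 higher (13 and 2, adjusted over the list alone); their median was -0.12 but their mean 0.01, and the falls included the folding enzyme PDIA4 (-0.25) and the signal peptidase subunit SPCS3 (-0.22). Memory or exit genes were higher (6 of 20, or 7 adjusted over the list alone; camera adjusted p = 0.00207), with TNFRSF13C, the BAFF receptor, at 0.36. Polycomb-silenced genes in germinal centre B cells were higher too (5 of 19, also 5 adjusted over the list alone; camera adjusted p = 0.0232), with FCRL5 at 0.73 and SLAMF1 at 1.25. For DOT1Li these 6 lists kept their calls with an estimated correlation, but narrowly, each at camera adjusted p = 0.0433. MHC class II genes (4 of 15 higher, 4 adjusted over the list alone; camera adjusted p = 0.00676) did not, at adjusted p = 0.52 with an estimated correlation, nor did cholesterol genes (8 of 24 lower, 13 adjusted over the list alone; camera adjusted p = 6.89e-07), at adjusted p = 0.209 with an estimated correlation. By line, without a test between lines, 6 MHC class II genes were called higher in Oci-Ly8 and 0 in each other line.

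EZH2i raised 2787 genes, among them genes that are silent or nearly so in DMSO, and lowered 2223. CYBB (ENSG00000165168, chromosome X, 37780018 to 37813461), the catalytic subunit of the phagocyte NADPH oxidase, fell by 1.93 ± 0.17 on the log2 scale (edgeR, adjusted p = 5.23e-12), from 133 ± 24.3 to 61.1 ± 7.3 CPM in Oci-Ly8 and from 11.8 ± 1.39 to 2.47 ± 0.25 CPM in Oci-Ly18 (SD, n = 3). Its partner NCF1 fell by 1.06, although reads of NCF1 can be shared with its pseudogenes. PRDM1 was 1.91-fold higher (0.93 ± 0.15), BCL2 rose by 0.62 and MS4A1, which encodes CD20, by 0.67. BCL6 (ENSG00000113916, chromosome 3, 187721377 to 187745725) rose by 0.24 on average, PAX5 by 0.18 and MYC by 0.20. XBP1 (-0.04), CIITA (0.06) and DOT1L (0.02) did not pass the test.

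Large average rises were those of ASAP2 (3.31), the RNA-binding protein IGF2BP2 (2.70), MCC (2.57) and the adhesion molecule NRCAM (2.44). Each of these 4 has no counts in the DMSO libraries of some line, so the averages depend on the prior count; in Oci-Ly7 ASAP2 was at least 26.9-fold and NRCAM at least 12.6-fold higher, and in Oci-Ly8 IGF2BP2 was at least 5.91-fold higher. Cell cycle genes fell (24 of 39, or 26 adjusted over the list alone; camera adjusted p = 7.21e-11), with CCNA2 at -0.23 and the helicase subunit MCM4 at -0.25, although this call was lost at adjusted p = 0.173 with an estimated correlation. Called falls were mostly in SUDHL6 (25) and Oci-Ly18 (21), against 1 lower in Oci-Ly8 and 2 higher in Oci-Ly7. MYC and nucleolar genes had 19 of 30 members lower and 1 higher (21 and 1, adjusted over the list alone; camera adjusted p = 9.6e-07, but adjusted p = 0.47 with an estimated correlation), and 20 were lower in SUDHL6 against at most 6 in another line. Polycomb-silenced genes had 8 of 19 higher and 1 lower (8 and 1, adjusted over the list alone; camera adjusted p = 0.016, but adjusted p = 0.0509 with an estimated correlation), with ABAT at 0.61 and TNFRSF21 at 0.48. Memory or exit genes had 6 of 20 higher and 1 lower (camera adjusted p = 0.0424, but adjusted p = 0.295 with an estimated correlation), and TNFRSF13C was 2.02-fold higher. Of 51 tested Polycomb developmental targets 5 rose (3, adjusted over the list alone), among them HOXC4 (0.69) and HOXC6 (0.78); 37 had no counts in some line, and averaged over lines with counts 14 rose. Their median was 0.42, and the camera adjusted p was 0.769. Interferon genes split, with 10 higher and 9 lower of 44 (11 and 9, adjusted over the list alone), such as OAS1 at -0.85 and ISG20 at -1.02; their median (0.10) and mean (0.24) were positive and their test pointed lower at a camera adjusted p of 0.868. In Oci-Ly8 25 interferon genes rose and in Oci-Ly18 23 fell.

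The combination gave the broadest change, with rises in PRDM1, memory or exit and Polycomb-silenced genes and falls in MYC or nucleolar genes and, in SUDHL6 and Oci-Ly18, cell cycle genes. PRDM1 was 3.5-fold higher (1.81 ± 0.14; edgeR, adjusted p = 1.65e-13), from 2.47 ± 0.45 to 34.7 ± 9.61 CPM in Oci-Ly7 (SD, n = 3). MX1 was 4.3-fold higher, USP18, a brake on interferon signalling, 4.04-fold and XAF1 4.18-fold. TNFRSF13C (ENSG00000159958, chromosome 22, 41922032 to 41926806) was 3.1-fold and KLF2, a factor of resting and recirculating lymphocytes, 3.65-fold higher. CYBB fell by 1.64 and JCHAIN by 0.94, while BCL2 was 1.88-fold higher.

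Germinal centre genes went both ways with the combination. Of 29 members 14 fell and 7 rose (14 and 8, adjusted over the list alone), with FOXO1, a factor of the dark zone, at -0.42, BCL7A at -0.41 and STAP1 at -0.49; the median was -0.15, the mean 0.07 and the camera adjusted p 0.101. BCL6 was at -0.17 on average (edgeR, adjusted p = 0.0255) and MYBL1 at -0.21, but both differed in direction between lines. Average log2 fold changes of other B cell genes were 0.33 for the early factor EBF1, 0.74 for MS4A1, 1.56 for the signalling adaptor BANK1 and -0.60 for the kinase SYK, and pan-B genes had 8 of 25 higher and 9 lower (9 and 10, adjusted over the list alone; camera adjusted p = 0.878). Plasma cell genes had 7 of 30 higher and 11 lower on average (the same counts adjusted over the list alone, and camera adjusted p = 0.761). On average PRDM1, the elongation factor ELL2 (1.41) and the stress sensor ERN1 (0.48) rose while XBP1 fell by 0.25. By line, without a test between lines, 4 plasma cell genes were higher and 15 lower in Oci-Ly7, and 9 and 7 in Oci-Ly8. In SUDHL6 the counts were 5 and 8, and in Oci-Ly18 11 and 4. IRF4 rose by 0.23 and CIITA, the activator of MHC class II genes, by 0.27. EZH2 fell by 0.26 ± 0.03 and DOT1L by 0.15 ± 0.04, and MYC fell by 0.21. PAX5 (0.07), CD38 (0.26) and CDKN1A (0.12) did not pass the test. SDC1 could not be called in the average of lines; in Oci-Ly8 its log2 fold change was 3.38.

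**Figure D3:**
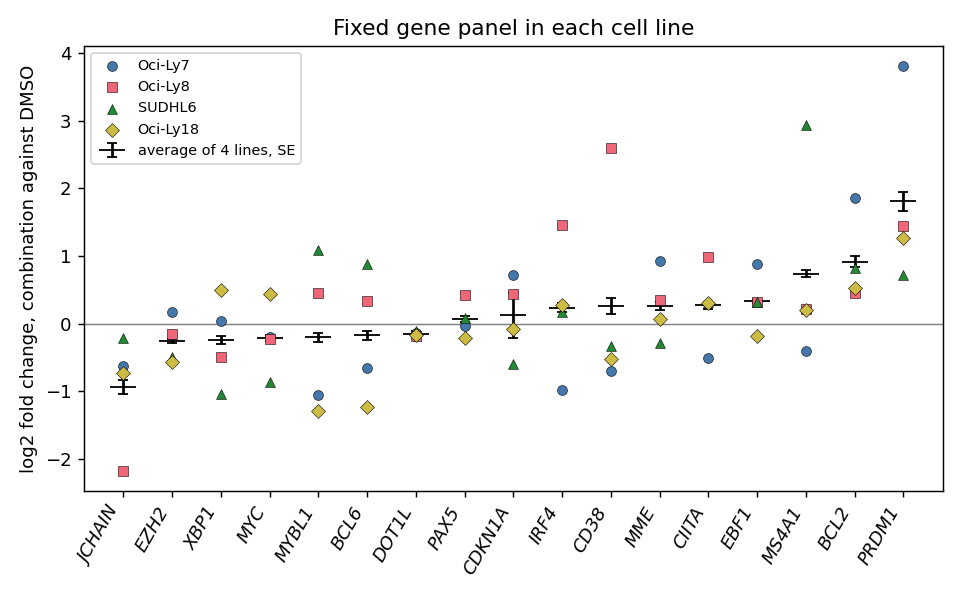
Log2 fold change, combination over DMSO (y axis), of the fixed panel genes reported here other than SDC1, with 1 point per cell line and a black bar for the average of 4 lines with its standard error. PRDM1 is higher in each line and 1.81 on average, whereas BCL6 and MYBL1 have lines on both sides of 0.

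Among called protein-coding genes with an average log2 CPM of at least 1 and the same sign in 4 lines, the largest average rises with the combination were MYOF (4.12 ± 0.53), NRCAM (4.02), MCC (3.87), ASAP2 (3.86) and SPTLC3 (3.70), whose averages rest partly on lines with few or no counts. Within the same limits the largest falls were CYBB, the signalling adaptor GRAP (-1.26), NCF1 (-1.10), PCED1B (-1.01) and the cytokine receptor IL21R (-0.95). Polycomb-silenced genes had 12 of 19 higher (12, adjusted over the list alone; camera adjusted p = 0.000243), with TNFRSF14, a receptor often lost in lymphoma, at 1.01 ± 0.09 and ABAT at 0.68. Memory or exit genes had 12 of 20 higher and 1 lower (13 and 1, adjusted over the list alone; camera adjusted p = 8.84e-05). In the cell cycle list 27 of 39 members fell and 1 rose (camera adjusted p = 3.31e-13), with MCM6 at -0.46 and CCNA2 at -0.39, and in the MYC and nucleolar list 29 of 30 fell (camera adjusted p = 1.58e-17), with NOLC1 at -0.52 and LDHA at -0.67. These 4 lists held with an estimated correlation, at camera adjusted p = 0.00302 for Polycomb-silenced and 0.0198 for memory or exit genes. Cell cycle (0.0483) and MYC and nucleolar genes (0.0421) held narrowly. Interferon genes had 31 of 44 higher and 4 lower (camera adjusted p = 1.31e-06, but adjusted p = 0.0874 with an estimated correlation). By line, without a test between lines, 35 were higher and 1 lower in Oci-Ly8 and 18 and 4 in Oci-Ly7. In Oci-Ly18 the counts were 13 and 9, and in SUDHL6 11 and 6. MHC class II genes had 11 of 15 higher and 1 lower (camera adjusted p = 0.000249, but adjusted p = 0.272 with an estimated correlation), with HLA-DQB1 at 0.79 and HLA-DPB1 at 0.47, genes whose reads can be shared between family members. Cholesterol genes had 16 of 24 lower and 2 higher (camera adjusted p = 0.00281, but adjusted p = 0.444 with an estimated correlation), with ACAT2 at -0.51. Stress genes had 15 of 26 lower and 1 higher (camera adjusted p = 8.92e-06, but adjusted p = 0.238 with an estimated correlation), with SLC7A5 at -0.80. Of 51 Polycomb developmental targets 12 rose (8, adjusted over the list alone; camera adjusted p = 0.587), including DLX2 (1.78) and HOXA7 (1.5); 34 had no counts in some line, and over lines with counts 22 rose and 1 fell.

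**Figure D4:**
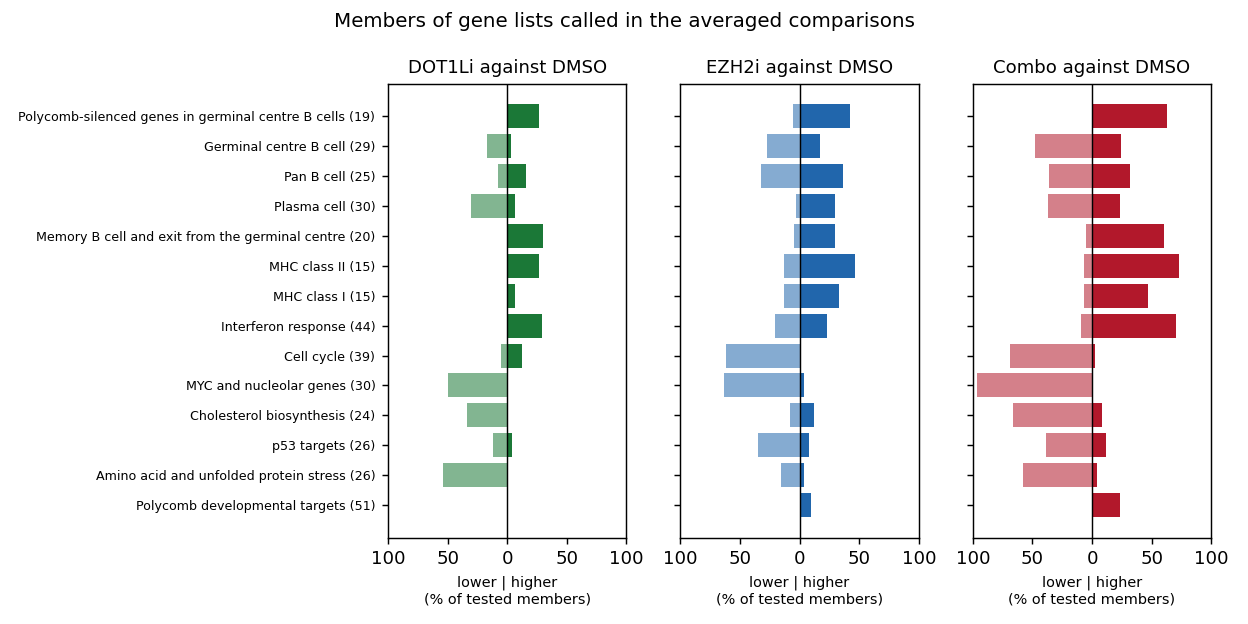
Percentage of the tested members of 14 gene lists (x axis) that were called higher (dark) or lower (light) than DMSO with DOT1Li, EZH2i and the combination. With the combination 29 of 30 MYC and nucleolar genes were lower and 31 of 44 interferon genes higher.

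The remaining lists did not pass camera's test in any comparison with DMSO. MHC class I had 7 of 15 members higher and 1 lower with the combination (camera adjusted p = 0.154), p53 targets 3 higher and 10 lower of 26 (0.134), with TP53INP1 at 1.24, PRC2 subunits 4 higher and 7 lower of 13 (0.134), with RBBP7 at -0.31, and DOT1L and its partners 5 higher and 2 lower of 15 (0.82). Markers of other cell types were sparse, since many were absent from the counts or had too few counts to test. T cell markers had 2 of 11 higher and 1 lower (0.82), NK and cytotoxic markers 2 of 5 higher (0.761), with NKG7 at 2.49, and myeloid markers 3 of 8 higher and 1 lower (0.878), with CSF1R at 2.99 on average and at least 9.45-fold higher in Oci-Ly7. Epithelial markers had 2 of 4 higher (0.759), fibroblast or endothelial markers 2 of 5 (0.154), with the collagen gene COL1A1 at 3.08, neuronal markers 1 of 3 (0.154) and erythroid or megakaryocytic markers the single tested gene ITGA2B (1.31; 0.802). COL1A1 went from 1.16 ± 0.38 to 5.21 ± 1.18 CPM in Oci-Ly18 (SD, n = 3).

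Comparing the combination with each single inhibitor asks what the second inhibitor adds. Against DOT1Li 3450 genes rose and 2802 fell, and against EZH2i 2274 rose and 2171 fell (edgeR). Of these, 675 and 20, and 401 and 6, had a log2 fold change of at least 1 in size; without SUDHL6 EZH2i replicate 3 the count of 6 was 2. PRDM1 was higher than with either inhibitor alone, by 0.78 ± 0.13 over DOT1Li and 0.87 ± 0.13 over EZH2i. Added to DOT1Li, EZH2i raised MYO15B (3.0), SMARCD3 (2.55), a chromatin remodelling subunit, the interferon-induced GTPase GBP5 (2.47), CD86 (1.09), a T cell costimulator, and KLF2 (1.70), and lowered CYBB (-1.69), SLAMF6 (-1.31) and CCNA2 (-0.34). Cell cycle genes were lower (34 of 39, or 35 adjusted over the list alone; camera adjusted p = 3.02e-23), and Polycomb-silenced genes (9 of 19 higher, 1 lower; 13 and 1, adjusted over the list alone; camera adjusted p = 0.000724) and memory or exit genes (8 of 20; camera adjusted p = 0.000724) were higher, all holding with an estimated correlation. Calls for MYC and nucleolar genes (22 of 30 lower; camera adjusted p = 6.48e-13), MHC class II (9 of 15 higher, 1 lower; 0.00171) and interferon genes (20 of 44 higher, 3 lower; 0.00286) were lost, at adjusted p = 0.0943, adjusted p = 0.414 and adjusted p = 0.392 with an estimated correlation.

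Added to EZH2i, DOT1Li raised interferon genes (33 of 44, or 35 adjusted over the list alone; camera adjusted p = 2.18e-19), with MX1 at 1.29 ± 0.11 and USP18 at 1.22, and memory or exit genes (8 of 20; camera adjusted p = 2.91e-05), with the phosphatase PTPN6 at 0.72. It lowered MYC and nucleolar genes (27 of 30; camera adjusted p = 1.59e-19) and stress genes (17 of 26, or 18 adjusted over the list alone; camera adjusted p = 8.23e-12), with the factor ATF5 at -0.57. Polycomb-silenced genes (8 of 19 higher, 1 lower; camera adjusted p = 0.00574) and fibroblast or endothelial markers (3 of 5 higher; camera adjusted p = 0.0105), with PECAM1 at 1.48 and VIM at 0.75, also passed. These 6 lists held with an estimated correlation. Calls for MHC class II (9 of 15 higher; camera adjusted p = 1.26e-05), cell cycle (19 of 39 lower; 2.01e-07), cholesterol (13 of 24 lower; 2.18e-06) and plasma cell genes (12 of 30 lower, 3 higher; 0.00155, median -0.14 and mean 0.07) were lost, at adjusted p = 0.15, adjusted p = 0.144, adjusted p = 0.18 and adjusted p = 0.131 with an estimated correlation. MYC fell by 0.41 and BCL6 fell by 0.41 relative to EZH2i alone (edgeR, adjusted p = 1.35e-09 and 4.31e-06). Among larger changes MYOF rose by 2.59 and LAMB1, a laminin, by 2.0, and the kinase gene BLK fell by 0.66.

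Whether both inhibitors act beyond the sum of their effects was tested directly. On average 4 genes were higher and 5 lower than the sum of log2 effects (edgeR), while 597 and 677 passed an unadjusted p under 0.05 and DESeq2 called 28 and 36. ADA2 (0.45), a secreted adenosine deaminase, LPIN1 (0.35), the carnitine acyltransferase CPT1A (0.44) and the antisense transcript GABPB1-AS1 (0.37) were above the sum. The cytoskeletal regulators ENAH (-0.45 ± 0.06), CORO1C (-0.23) and CORO2B (-0.52), FAM81A (-0.50) and the replication factor RFC3 (-0.22) were below it. CPT1A, GABPB1-AS1 and CORO2B were named after their values were seen. These counts rest on single libraries. The number above the sum was 17 without Oci-Ly8 DMSO replicate 3, 15 without replicate 2 and 2 without replicate 1 of that group, 11 without Oci-Ly7 combination replicate 1, 8 without SUDHL6 combination replicate 3, 7 without SUDHL6 EZH2i replicate 2, and 2 without Oci-Ly8 EZH2i replicate 3, SUDHL6 DMSO replicate 2, EZH2i replicate 1 or combination replicate 2, or Oci-Ly18 DOT1Li replicate 2 or EZH2i replicate 2. The number below it was 17 without Oci-Ly8 DMSO replicate 2, 16 without Oci-Ly7 combination replicate 1, 10 without Oci-Ly8 DMSO replicate 3, and 3 without SUDHL6 DOT1Li replicate 3, EZH2i replicate 1 or combination replicate 2. PRDM1 was at -0.15 ± 0.20 and did not pass. As a list, cell cycle genes lay below the sum (median -0.10; camera adjusted p = 1.15e-19, holding with an estimated correlation), with 13 members lower when adjusted over the list alone. The other 6 lists that passed camera's test lost the call with an estimated correlation: interferon (median 0.23; camera adjusted p = 2.05e-07, then adjusted p = 0.132 with an estimated correlation), MYC and nucleolar (-0.08; 1.88e-08, then 0.18), MHC class II (0.09; 0.000205, then 0.209), pan-B (-0.06; 0.000486, then 0.146), stress (-0.07; 0.00914, then 0.409) and memory or exit genes (0.20; 0.0139, then 0.159).

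The overlap of the single inhibitors asks whether DOT1L and EZH2 inhibition change the same genes. Of the genes raised by DOT1Li 52.6% were also raised by EZH2i, and of the genes raised by EZH2i 17.01% were also raised by DOT1Li. In all 474 rose and 385 fell with both, where independence would give 141.6 and 115.5, and 179 went in opposite directions. Shared rises included CMPK2 (2.14 with DOT1Li, 2.37 with EZH2i) and TANC1 (1.71 and 2.43), and shared falls included ALDOC (-0.56 and -0.39) and EVI2A (-0.53 and -0.51). Both effects use the same DMSO libraries. Splitting these leaves a single DMSO library in each line for 1 of the inhibitors. In Oci-Ly8 the single library was DMSO replicate 3, which was low in long transcripts, so its difference from its group enters both splits. With 6 separate DMSO libraries for each inhibitor, 256 genes rose and 132 fell with both in a split of the controls and 356 and 310 in the reverse split, against 95.3 and 83.3, and 118.2 and 89.0, under independence. Opposite changes numbered 242 and 125. Without Oci-Ly8 DMSO replicate 1 the 385 shared falls were 660. Across genes the effects had a Pearson correlation of 0.548, against at most 0.517 in 20 simulations without any effect; genes are not independent replicates.

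Line by line, DOT1Li raised 306 and lowered 208 genes in Oci-Ly7, 627 and 484 in Oci-Ly8, 489 and 374 in SUDHL6 and 716 and 376 in Oci-Ly18 (edgeR). EZH2i raised 1559 and lowered 874, 1605 and 1409, 2493 and 1538, and 2301 and 1605, and the combination 3134 and 2163, 3215 and 2995, 4005 and 2973, and 3740 and 2477, in the same order. Counts for DOT1Li in single lines rest on few libraries. In Oci-Ly7 524 rose and 453 fell without DOT1Li replicate 1, 81 and 34 without replicate 2, 134 and 66 without replicate 3, and 196 and 112, 170 and 115, and 168 and 130 without DMSO replicates 1, 2 and 3. In Oci-Ly8 407 rose and 311 fell without DOT1Li replicate 1, 385 and 239 without replicate 2, and the falls numbered 949 without replicate 3 and 783 without DMSO replicate 1. In SUDHL6 265 rose and 141 fell without DOT1Li replicate 1, 269 and 158 without replicate 2, 267 and 144 without DMSO replicate 1 and 300 and 243 without replicate 3, and the falls numbered 243 without DMSO replicate 2 and 562 without Oci-Ly8 DMSO replicate 3. Falls in Oci-Ly18 numbered 238 without DOT1Li replicate 1 and 250 without DMSO replicate 2. For EZH2i the falls in Oci-Ly8 numbered 2151 without DMSO replicate 1, 696 without DMSO replicate 3, 929 without EZH2i replicate 1 and 860 without EZH2i replicate 3. A separate fit of Oci-Ly8 alone called 225 higher and 71 lower with DOT1Li and 1978 and 1469 with the combination. Without the 2 Oci-Ly8 libraries low in long transcripts, DOT1Li raised 849 and lowered 845 genes in SUDHL6, and without the 2 Oci-Ly7 libraries with a weaker DOT1Li response (replicate 1 of DOT1Li and of the combination) it raised 541 and lowered 472 in Oci-Ly7.

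Genes called in the same direction in all 4 lines numbered 4 higher and 2 lower for DOT1Li, 125 and 43 for EZH2i, and 344 and 340 for the combination, where independence would give 26.99 and 8.53 for the last. The 6 genes of DOT1Li are the surface proteins ADGRB2, PLXNB1, DDR1 and CHL1, which rose, and the signalling GTPase RHOH and the DNA repair gene UIMC1, which fell; CHL1 rose by between 0.75 and 3.52, and all but CHL1 were named after their values were seen. Rises numbered 1 without Oci-Ly7 DOT1Li replicate 2 or 3 or Oci-Ly18 DOT1Li replicate 3, and no fall was left without Oci-Ly7 DOT1Li replicate 2, SUDHL6 DMSO replicate 2 or SUDHL6 DOT1Li replicate 1. For EZH2i the 43 were 28 without Oci-Ly18 DMSO replicate 2.

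With the combination, responses of named genes were often specific in size to a line. In Oci-Ly7 DTNA and ASAP2 were at least 185-fold and 121-fold higher, and the Toll-like receptor homologue CD180 fell by 2.96. In Oci-Ly8 TMEM119 (7.57 ± 0.39) and BAHCC1 (7.33) rose and FGD5 fell by 3.31. SUDHL6 gained ALDH1A1, a retinal dehydrogenase, by at least 178-fold and the granzyme gene GZMA (6.23), and its cholesterol exporter gene ABCG1 fell by 2.29. Oci-Ly18 gained SFRP5 (6.13) and the B cell precursor gene DNTT (5.74), and its FCRL1 fell by 2.70. The F test of the difference between lines called 913 genes for DOT1Li, 4266 for EZH2i and 7780 for the combination; for DOT1Li it called 1400 without the 2 Oci-Ly8 libraries low in long transcripts. Genes with the smallest p included HMCES for DOT1Li, from -0.40 in Oci-Ly18 to 1.04 in Oci-Ly8, NME4 for EZH2i, and AKAP12 for the combination, from -0.88 in Oci-Ly18 to 5.70 in Oci-Ly8. MX1 with the combination went from 12.2 ± 4.93 to 217 ± 43.2 CPM in Oci-Ly8 and from 9.02 ± 0.17 to 19.3 ± 1.47 CPM in SUDHL6 (SD, n = 3). BCL6 went from 15.1 ± 1.51 to 27.8 ± 2.94 CPM in SUDHL6 and from 179 ± 15.6 to 75.8 ± 8.87 CPM in Oci-Ly18. Of the 15 MHC class II genes 11 were lower in Oci-Ly7, against 13 higher and 1 lower in SUDHL6, 12 and 1 in Oci-Ly8 and 6 higher in Oci-Ly18. The cell cycle list had 33 of 39 members lower in each of SUDHL6 and Oci-Ly18. It had 7 lower and 7 higher in Oci-Ly7 and 5 lower and 7 higher in Oci-Ly8. These list counts were not tested between lines.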

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

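By an F test the lines differed in their response to each of the treatments, genes of B cell identity included. Other splits of the libraries cannot decide whether chance gives as many differences. The tests of library depth and of a shared replicate number, the count of rises after length correction and the tests on other splits of the libraries were chosen only after the results were seen.

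By edgeR's F test the effect of DOT1Li differed between the 4 lines for 913 genes, that of EZH2i for 4266 and that of the combination for 7780 of 17749. It passed for 24 of 71 genes named for the averaged comparison with DOT1Li, 58 of 81 with EZH2i and 72 of 87 with the combination; most were named for a called effect on average, so these shares do not stand for all genes. Genes called higher in a line and lower in another numbered 85 with DOT1Li, 701 with EZH2i and 1712 with the combination. Of the fixed panel, DOT1Li moved MYBL1 from -0.76 to 0.56 on the log2 scale across lines, a spread of 1.32, and IRF4 from -0.60 to 0.55, a spread of 1.15. With EZH2i the spread between the lowest and highest line was 1.2 for BCL6 (-0.34 to 0.87), 1.6 for MYBL1, 1.44 for IRF4 and 0.74 for CIITA. Genes of antibody secretion parted as well, with spreads of 1.61 for XBP1, 2.17 for SDC1, 1.87 for JCHAIN and 1.99 for CD38, and MYC had 0.988. The combination gave BCL6 a spread of 2.12 (-1.24 in Oci-Ly18 to 0.88 in SUDHL6), MYBL1 2.39 (-1.30 to 1.09), MS4A1 3.34 (-0.40 in Oci-Ly7 to 2.94 in SUDHL6), MME 1.2, EBF1 1.06 and EZH2 itself 0.739. IRF4 spread by 2.44, XBP1 by 1.54, SDC1 by 3.75, CD38 by 3.31 (-0.71 in Oci-Ly7 to 2.60 in Oci-Ly8), CIITA by 1.5 and MYC by 1.31. Each of these genes was called in both directions in single lines. Why the lines differ was not tested.

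The first pattern weighed is technical in form: Oci-Ly8 DMSO replicate 3 and DOT1Li replicate 3 had fewer counts from long transcripts, with length slopes of -0.223 and -0.195 against at least -0.0482 in the others. Depth is argued against, since 8 other libraries had fewer counts than Oci-Ly8 DMSO replicate 3 and none of those had a slope under -0.0289. A condition shared by all Oci-Ly8 libraries numbered 3 is argued against as well, since EZH2i replicate 3 and combination replicate 3 had slopes of 0.0357 and 0.0356. Length alone does not account for their distance from their groups, which fell from 0.293 to 0.227 (median absolute log2 difference) after a length correction and stayed above the highest of the other 14 groups (0.096). What else sets these libraries apart stays open, and no biological explanation was tested.

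The second pattern is that rises made up 97.8% of the called changes with a log2 fold change of at least 1 in size under the combination. Scaling would have to be off by 0.636 on the log2 scale to even the numbers, whereas TMM and DESeq2 size factors differed by 0.0148. Both scalings assume that most genes are unchanged, so an error common to both would not show here. Among genes with an average log2 CPM of at least 3 rises were 98% (287 against 6). That average runs over all lines, so genes near 0 with DMSO in a line can pass, and low counts there are not excluded. Transcript length does not carry the excess, since rises were 98.3% (1510 against 26) with a length correction. No biological explanation was tested. The excess was not limited to EZH2 inhibition, since DOT1Li alone had 123 rises and 5 falls of that size.

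Other splits of the libraries were used to ask whether chance could give as many called genes; each test used 100 splits within lines, the real one included. Chance can be excluded for the averaged counts of DOT1Li (1824, highest other 805), EZH2i (5010, 829), the combination (8236, 2194), the combination against DOT1Li (6252, 1266) and against EZH2i (4445, 1291), each reached in 1 of 100 splits. Genes called in all 4 lines (6, 168 and 684 for the 3 treatments, highest other 0) and the overlap of both inhibitors (859, highest other 208) were also reached in 1 split. The averaged comparisons had a median of 0 calls in the other splits, which leaves little to share. Whether lines or inhibitors share genes beyond chance is therefore not decided by these splits. For differences between lines, the 4266 genes of EZH2i were reached in 2 of 100 splits (highest other 4360). The 7780 of the combination were reached in 1 (highest other 6724) and the 913 of DOT1Li in 20 (highest other 3168). Labels were swapped separately in each line, so a split can turn a treatment effect into a difference between lines. The splits therefore cannot decide whether chance gives as many differences. Chance is not excluded for non-additivity on average (9 genes, reached in 6 splits, highest other 133). Nor is it within Oci-Ly7 (9, 14 splits, highest other 1559), Oci-Ly8 (18, 18 splits, 2568), SUDHL6 (4, 19 splits, 1155) or Oci-Ly18 (64, 15 splits, 1414). For non-additivity the labels of all 4 treatments were swapped, so a split can carry treatment effects into this contrast. These splits are therefore not a set without effects and do not show that the real non-additivity counts arose by chance.

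Within a line 10 splits are too few for a test. For DOT1Li the real counts and the highest other splits were 514 and 1 in Oci-Ly7, 863 and 0 in SUDHL6 and 1092 and 0 in Oci-Ly18, and in Oci-Ly8 1111 and 3703, where 5 of 10 splits reached the real count; the split with 3703 sets the 2 libraries low in long transcripts apart. For EZH2i they were 2433 and 0, 3014 and 40, 4031 and 0, and 3906 and 0, and for the combination 5297 and 0, 6210 and 6, 6978 and 0, and 6217 and 0, in the order Oci-Ly7, Oci-Ly8, SUDHL6, Oci-Ly18.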

How the results depend on the processing

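The rise of PRDM1 with the combination kept its call under every setting tried, and the memory or exit and cell cycle lists under the 3 other settings of the list test, where the interferon list lost its call in 1. The cell cycle list was close to the threshold with an estimated correlation (camera adjusted p = 0.0483). Counts of non-additive genes and of DOT1Li effects in single lines did not keep their size. Leaving out pairs of Oci-Ly8 or Oci-Ly7 libraries, the length correction and the averaging over lines with counts were chosen only after the results were seen. A count is called changed here when it moved by more than 1.5 times, large means a log2 fold change of at least 1 in size, the value in brackets is the one reported, and rises and falls from additivity are genes above or below the sum. Except where said, the cause of a change was not tested.

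Of the 1824, 5010 and 8236 genes called for DOT1Li, EZH2i and the combination, DESeq2 called 1801, 4961 and 8021 as well, edgeR with DESeq2 size factors 1710, 4913 and 7990, and edgeR without a filter on low counts, which tests more genes, 1420, 4218 and 7547. No gene among them changed sign in these 3 runs. The additive model called only 868, 3943 and 7242 of them and changed the sign of 6, 16 and 44, and the length correction called 1664, 4651 and 7424 and changed the sign of 26 with the combination. With single libraries left out, at least 1467 (80.4%) of the 1824 were kept, fewest without Oci-Ly7 DOT1Li replicate 3, and at least 91.7% and 94.9% were kept for EZH2i and the combination. Values of named genes kept direction and call in 20983 refits without a library, lost the call in 212 and gained it in 21. In the additive model 80 of these values lost the call and 3 gained it. Without a filter on low counts 13 lost it and 5 gained it, and with the length correction 8 and 3.

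With DESeq2, large rises with DOT1Li numbered 191 (123) and the difference between lines for DOT1Li 1388 (913). Its non-additive genes were 28 (4) above and 36 (5) below the sum on average, with 1 (0) large rise, 19 (7) and 17 (2) in Oci-Ly7, 23 (9) and 15 (9) in Oci-Ly8, 60 (37) and 64 (27) in Oci-Ly18, and 7 (4) below it in SUDHL6. Above the sum in SUDHL6 edgeR and DESeq2 each called 0, with 245 and 229 at an unadjusted p under 0.05. With DESeq2 size factors in edgeR, the 2 genes below the sum in Oci-Ly7 became 0, with 410 at an unadjusted p under 0.05, and the 2 falls shared by all lines with DOT1Li became 1.

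Without a filter on low counts, large falls numbered 48 (25) with EZH2i, 75 (31) with the combination, and 34 (20) and 13 (6) for the combination against DOT1Li and EZH2i. Non-additive genes were 34 (4) and 25 (5) on average with 3 (0) large rises, 32 (7) and 44 (2) in Oci-Ly7, 39 (9) and 19 (9) in Oci-Ly8, 84 (37) and 58 (27) in Oci-Ly18, and 14 (4) below the sum in SUDHL6. Genes called in all lines numbered 12 (4) higher with DOT1Li and 22 (43) lower with EZH2i.

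An additive model, in which differences between lines go into the spread, gave large rises of 322 (123) with DOT1Li, 790 (449) with EZH2i and 616 (401) for the combination against EZH2i. Large falls were 12 (5), 83 (25) and 103 (31) for the 3 treatments, and 51 (20) and 26 (6) for the combination against DOT1Li and EZH2i. Falls with DOT1Li numbered 556 (922). Shared falls of both inhibitors numbered 229 (385) and opposite changes 70 (179). It called 0 (4) genes above and 0 (5) below the sum, with 390 and 320 at an unadjusted p under 0.05. VIM, at 0.48 for the combination against DOT1Li, reversed to -0.087 in this model without passing the test (adjusted p = 0.568).

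Averaging over the lines with counts raised large calls by its construction, since more genes can be called: DOT1Li 258 (123) rises and 8 (5) falls, EZH2i 771 (449) and 45 (25), and falls of 54 (31) with the combination, 35 (20) for it against DOT1Li and 10 (6) against EZH2i. Correcting for gene length gave 3 (5) large falls with DOT1Li, 8 (4) genes above the sum on average and 4 (2) below it in Oci-Ly7.

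Leaving out Oci-Ly8 DMSO replicate 3 and DOT1Li replicate 3 gave non-additive genes of 33 (4) and 19 (5) on average, 26 (7) and 20 (2) in Oci-Ly7 and 64 (37) and 56 (27) in Oci-Ly18. DOT1Li then had 460 (306) rises and 490 (208) falls in Oci-Ly7, 849 (489) and 845 (374) in SUDHL6 and 652 (376) falls in Oci-Ly18, and its difference between lines 1400 (913). Falls with EZH2i were 1534 (874) in Oci-Ly7, 858 (1409) in Oci-Ly8 and 2335 (1538) in SUDHL6. Falls in all lines numbered 5 (2), 94 (43) and 524 (340) for the 3 treatments, shared falls 635 (385) and opposite changes 279 (179). Without DOT1Li replicate 1 and combination replicate 1 of Oci-Ly7, DOT1Li had 541 (306) rises and 472 (208) falls there, non-additive genes were 11 (4) and 15 (5) on average and 17 (7) and 32 (2) in Oci-Ly7, and 9 (4) rises and 4 (2) falls with DOT1Li were shared by all lines.

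A separate fit for each line, which uses that line's own spread, gave DOT1Li 225 (627) rises and 71 (484) falls in Oci-Ly8, 944 (489) and 1110 (374) in SUDHL6, and 1102 (716) and 905 (376) in Oci-Ly18. EZH2i had 723 (1605) rises and 286 (1409) falls in Oci-Ly8 and falls of 1491 (874) in Oci-Ly7, 2819 (1538) in SUDHL6 and 2784 (1605) in Oci-Ly18, and the combination 1978 (3215) and 1469 (2995) in Oci-Ly8. Non-additive genes were 3 (7) and 0 (2) in Oci-Ly7, 0 (9) and 0 (9) in Oci-Ly8, 1 (0) and 10 (4) in SUDHL6, and 165 (37) and 145 (27) in Oci-Ly18; at an unadjusted p under 0.05 edgeR had 505 below the sum in Oci-Ly7 and 331 above and 186 below it in Oci-Ly8. Falls in all lines became 1 (2) with DOT1Li and 19 (43) with EZH2i.

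The labels do not say whether replicate numbers pair libraries, but 48 of 48 libraries correlated best with libraries of their own number in their line, which is a hint of pairing. Of 72 pairs of the same number 17 had a correlation over 0.1 (0.0195 to 0.415, median 0.0633). All 3 pairs exceeded it for DMSO with DOT1Li in Oci-Ly8, DOT1Li with the combination in Oci-Ly7 and EZH2i with the combination in SUDHL6. A replicate block gave more calls: DOT1Li falls 1397 (922) on average, 560 (306) rises and 496 (208) falls in Oci-Ly7, 890 (489) and 842 (374) in SUDHL6, falls of 845 (484) in Oci-Ly8 and 656 (376) in Oci-Ly18, and a difference between lines of 1802 (913). EZH2i falls in Oci-Ly7 numbered 1386 (874). Non-additive genes with the block were 40 (4) and 57 (5) on average with 1 (0) large rise, 36 (7) and 50 (2) in Oci-Ly7, 32 (9) and 33 (9) in Oci-Ly8, 2 (0) and 16 (4) in SUDHL6 and 102 (37) and 98 (27) in Oci-Ly18. Genes of all lines were 11 (4) and 14 (2) with DOT1Li and 200 (125) and 92 (43) with EZH2i, shared falls 650 (385) and opposite changes 334 (179). Blocked camera tests passed for plasma cell genes (adjusted p = 0.0469, from 0.0757) and MHC class II genes (0.041, from 0.154) with EZH2i and for stress genes in the combination against DOT1Li (0.0394, from 0.0685). Camera with an estimated correlation and no block gave adjusted p = 0.698, 0.744 and 0.593 for them, in the same order.

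Stricter thresholds give fewer shared genes by construction. At an adjusted p under 0.01 those of all lines were 0 (4) and 0 (2) with DOT1Li, 54 (125) and 13 (43) with EZH2i and 171 (344) and 153 (340) with the combination, and the overlap held 252 (474) rises, 183 (385) falls and 87 (179) opposite changes. With large changes alone they were 0 (4) and 0 (2), 2 (125) and 1 (43), and 67 (344) and 2 (340), and the overlap held 57 (474), 0 (385) and 0 (179). Clustering by line did not change. Within Oci-Ly8 the adjusted Rand index against treatment was 0.377 with fewer genes and 0.639 with more genes, Ward linkage or Euclidean distance (0.543), and in SUDHL6 it was 1 (0.543) with Ward linkage or Euclidean distance.

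Camera with an estimated correlation gave larger adjusted p-values for the lists, and 23 of 138 list results lost their call. For DOT1Li these were MHC class II (0.52, from 0.00676) and cholesterol (0.209, from 6.89e-07). For EZH2i they were Polycomb-silenced (0.0509, from 0.016), memory or exit (0.295, from 0.0424), cell cycle (0.173, from 7.21e-11) and MYC and nucleolar genes (0.47, from 9.6e-07). For the combination they were MHC class II (0.272, from 0.000249), interferon (0.0874, from 1.31e-06), cholesterol (0.444, from 0.00281) and stress genes (0.238, from 8.92e-06). Against DOT1Li MHC class II (0.414), interferon (0.392) and MYC and nucleolar genes (0.0943) were lost, and against EZH2i plasma cell (0.131), MHC class II (0.15), cell cycle (0.144) and cholesterol genes (0.18). Of the non-additivity lists pan-B (0.146), memory or exit (0.159), MHC class II (0.209), interferon (0.132), MYC and nucleolar (0.18) and stress genes (0.409) were lost.

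Leaving out single libraries moved large falls with DOT1Li between 2 and 7 (5) and those of the combination against EZH2i between 2 and 9 (6). Non-additive genes lay between 2 and 17 (4) above, 0 and 1 (0) large, and 3 and 17 (5) below the sum on average. In Oci-Ly7 they lay between 5 and 31 (7) and between 0 and 49 (2), both highest without combination replicate 1, in Oci-Ly8 between 1 and 101 (9) and between 2 and 89 (9), both highest without DMSO replicate 2, in SUDHL6 between 1 and 4 (4) below and in Oci-Ly18 between 24 and 48 (37) above, lowest without EZH2i replicate 2. DOT1Li rises and falls lay between 81 and 524 (306) and between 34 and 453 (208) in Oci-Ly7, 385 and 891 (627) and 239 and 949 (484) in Oci-Ly8, and 265 and 624 (489) and 141 and 562 (374) in SUDHL6, and its falls in Oci-Ly18 between 238 and 481 (376); the libraries are named in the report. EZH2i falls in Oci-Ly8 lay between 696 and 2151 (1409). For all lines, DOT1Li rises lay between 1 and 6 (4), its falls between 0 and 4 (2) and EZH2i falls between 28 and 61 (43), and shared falls of both inhibitors between 317 and 660 (385). In Oci-Ly7 the count below the sum, 0 in some of these refits, had 458 genes at an unadjusted p under 0.05 with all libraries.

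Depth limits what can be seen of silent genes. Oci-Ly8 DOT1Li, with the shallowest library, has a floor of 0.105 CPM, and 2048 of 17749 genes had no counts in a line for the combination, and none of those was called.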

Other observations

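With the combination, genes of early B cell development mostly rose in Oci-Ly7 and Oci-Ly8 and went both ways in SUDHL6 and Oci-Ly18, where several were already high with DMSO. The genes of the precursor list, IGLL1 and DNTT among them, and the class counts were chosen only after values of the comparisons had been seen; the tests of the other precursor genes, of material from other lines and of likeness between lines had their outcomes named in advance. IGLL1, the surrogate light chain gene of pre-B cells, rose by 3.55 ± 0.16 on the log2 scale on average (edgeR, adjusted p = 1.52e-19), from 0.128 ± 0.016 to 51.6 ± 19.2 CPM in Oci-Ly7 and from 0.456 ± 0.25 to 22.6 ± 4.67 CPM in Oci-Ly8 (SD, n = 3). SUDHL6 and Oci-Ly18 already had 276 and 396 CPM with DMSO and 250 and 440 CPM with the combination. DNTT, the polymerase that adds bases at antibody gene joints, rose by 2.76 on average and went from 3.94 to 46.3 CPM in Oci-Ly8 and from 0.101 to 6.03 CPM in Oci-Ly18, but from 1190 to 630 CPM in SUDHL6. RAG2, a subunit of the recombinase, went from 1.25 to 55.9 CPM in Oci-Ly7.

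Of 11 other precursor genes 7 were called higher on average with the combination, 3 with DOT1Li and 2 with EZH2i. Called members by line, without a test between lines, were 8 higher in Oci-Ly7 and 6 higher and 1 lower in Oci-Ly8. In SUDHL6 2 were higher and 4 lower, and in Oci-Ly18 3 were higher and 4 lower. RAG1 fell in SUDHL6 from 472 to 164 CPM and rose in Oci-Ly7 from 0.173 to 4.45 CPM. Material of SUDHL6 or Oci-Ly18 in the libraries of Oci-Ly7 and Oci-Ly8 is argued against: genes specific to those lines put its median share at no more than 0.0819%, where IGLL1 would need at least 5.14%. A rise of precursor genes in Oci-Ly7 and Oci-Ly8 may therefore be real, as a hypothesis found and tested on the same data, although some of them, such as RAG1 at 179 CPM in Oci-Ly8, were not low with DMSO.

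By gene class, 618 of 2669 long noncoding RNAs rose with the combination and 115 fell, whereas 15 of 800 processed pseudogenes rose and 97 fell; among 13502 protein-coding genes 3789 rose and 3408 fell. Reads of a processed pseudogene can come from its parent gene.

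A further hypothesis was that treatment makes the lines more alike. The variance between line means, over 17749 genes, relative to DMSO was 1.01 with DOT1Li (0.999 to 1.01 without a replicate number), which does not settle it, 1.01 with EZH2i (1 to 1.01), which argues against it, and 0.993 with the combination (0.988 to 0.997), the direction the hypothesis needs. The last change is under 1%, so the lines remained nearly as far apart as with DMSO.

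In Oci-Ly7 the DOT1Li response was weaker in replicate 1. On 235 genes higher and 118 lower with DOT1Li in at least 2 of the other lines, DOT1Li replicate 1 scored 0.0805 (mean log2 change) against a mean of 0.259 for the other replicates, and combination replicate 1 scored 0.366 against 0.521. That combination library also had a lower EZH2i score, 0.848 times the mean of the other replicates. The EZH2i score also moved with DOT1Li alone, at 0.0457, 0.074 and 0.0786 in replicates 1, 2 and 3, against -0.0135 to 0.0266 with DMSO. A weaker DOT1Li response could therefore lower it, and whether the weaker response is limited to DOT1Li stays open. On the DOT1Li score DMSO libraries reached at most 0.0115 and EZH2i libraries 0.137 to 0.163.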
